A study of Homo sapiens with 12 samples.

How the data were processed

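Gene expression was measured by RNA sequencing in mesenchymal stem cells (MSC) derived from the human embryonic stem cell line H9, in 12 libraries that form 6 groups of 2. The cells either carried the unedited NRF2 gene (WT) or were homozygous for a knock-in of a single-nucleotide change that the labels call A245G (AG). NRF2, encoded by NFE2L2, is a transcription factor that switches on antioxidant and detoxification genes. The labels do not say from where the position in A245G is counted. MSC were taken at early or at late passage, and a transformed line of each genotype was made, per the labels' protocols, by a serial transduction that included telomerase (TERT), viral T antigens and an oncogenic form of HRAS. MSC were grown with basic fibroblast growth factor at 10 ng/mL, and transformed cells without it. Each genotype is its own edited or unedited line, and the labels do not give the number of clones, so a genotype difference is also a difference between lines. The labels call the 2 libraries of a group duplicates and do not say that they came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

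Total RNA was extracted with a column kit and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Reads were aligned with TopHat and quantified with Cufflinks on the human genome build hg19 (GRCh37), per the submitters' processing notes. The versions, the gene annotation, the strand setting and any masking of ribosomal RNA are not given in the sources used here. Without a stated strand setting, a gene and an overlapping or antisense partner cannot be told apart. The deposited values are FPKM (fragments scaled to transcript length and to the mapped fragments of the library) made by the authors for each gene and library, with the lower and upper bound of an interval around each FPKM and a status, per the file headers. All 12 tables hold 25277 lines with the same 23616 gene symbols, of which 554 stand on more than 1 line. No library was pooled with another in these tables, per the file headers. Symbols and loci are given as in the files, with loci in hg19, and the reference genome of another build was not used here.

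The FPKM of symbols on several lines were summed. Lines with the status HIDATA in any library (3 lines at a ribosomal RNA repeat, 2 of them the only line of their symbol) were left out, which left 23614 symbols. A symbol was tested when it reached an FPKM of 1 in at least 2 libraries, which gave 12430 genes. Fits used log2(FPKM + 1), so fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low FPKM. Values were used as deposited, with no further scaling. A linear model with a mean for each of the 6 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend). It has 6 residual degrees of freedom, and the prior added 4.44 at the median gene. All adjusted p-values of single genes are limma's, with Benjamini-Hochberg adjustment over the tested genes of a comparison, and a gene was called changed below 0.05. No count model was run, since the tables hold no counts. Tables were joined with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with Matplotlib 3.10.9.

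Depth was read from the deposited intervals. If a value's spread is that of counting, the square of the FPKM over its SD (with the interval taken as 2 SD each way) is the number of fragments behind it. Summed over genes, this gave 4.64 M to 7.44 M effective fragments per library (M, mega), with relative depths from 1.00 to 1.42. Among low values, 50.5% to 52.6% came out whole within a tolerance of 0.03, so whole reads were not recovered and these numbers serve only as a guide to precision. An FPKM of exactly 0 can be a failed estimate. In the report, genes at 0 in both libraries of a compared group are described as listed at 0, with values of single libraries and no fold in the text.

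There were 9 comparisons. AG was compared with WT at early passage, at late passage and after transformation, and late with early passage and transformed with early-passage MSC within each genotype. Both differences between genotypes of these changes (the interactions) were tested in the same fit. The genes named are the 6 largest increases and the 6 largest decreases of a comparison (4 for an interaction) among called genes whose libraries do not overlap between the groups and whose higher group has a mean FPKM of at least 5. Symbols of small RNAs, ribosomal proteins, uncharacterised or hyphenated symbols and symbols on several lines were left out of this rule. NFE2L2 was always named, TERT and HRAS were named for transformation, and from each list up to 4 members with the smallest adjusted p. Some genes, such as early-passage NQO1 and GCLM, were named outside this rule. Some genes that the rule or a list takes in, and 1 list, are not reported here. Not every called list of a comparison is described.

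Gene lists came to 29, of which 23 were pathways and 6 were markers of other cell types. The 22 pathway lists reported were NRF2 targets, proteasome subunits, mitosis, DNA replication, secreted factors of senescent cells, nuclear lamina and heterochromatin, RAS and MAPK output, extracellular matrix, contractile smooth muscle genes, TGF-beta and YAP targets, MSC surface markers, osteogenic and chondrogenic genes, adipogenic genes, interferon response, unfolded protein response and ATF4, heat shock, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, immediate early genes and HOX genes. The cell type lists were pluripotent, epithelial, endothelial, neural, haematopoietic and skeletal muscle markers. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, again with the correlation estimated from the data, and by fry, which tests whether a list's genes move on balance in one direction. List calls given here are camera's. Each p was adjusted over the 29 lists of a comparison. Calls were also counted with p adjusted over the list alone. Among the lists reported, the NRF2 target list (early passage and transformed) and the HOX list (transformed) kept a camera call with an estimated correlation, and every other list call given here rests on the preset correlation.

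The overlap of calls between comparisons was set beside the product of the call counts over the genes tested. The passage change in AG was regressed on that in WT, and the same value was simulated 100 times with no genotype effect. Intervals of list medians are 95% bootstrap intervals over 10000 draws of the list's genes. The fit was tested on simulated data for the early-passage genotype comparison with all 12430 genes. It recovered 72.8% of genes changed by 0.5 (log2), 95.2% of those changed by 1 and 99.7% of those changed by 2, and 6.30% of the calls were false. Duplicates correlated at 0.9885 to 0.9918 (log2). Their median squared difference was 1.13 to 1.42 times that of counting error (mean 1.35 to 4.14), so technical repeats cannot be excluded.

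The alternatives tried were a pseudocount of 0.1, no filter or a filter at an FPKM of 5, median-ratio scaling, quantile normalization, no variance trend, the replicate number as a block, fits of only the groups compared, late passage as the reference for transformed cells and leaving out each library in turn. Added after seeing the data were runs without symbols on several lines, without lines marked FAIL (25 lines) and, for the NRF2 targets, without members that have near copies. Median-ratio scaling shifted gene changes by a median of 0.14 (log2) between late and early WT and of -0.12 between transformed and early WT. The median change of all genes was -0.11 and 0.11 as deposited and 0.01 and 0.00 with this scaling, so list changes there are also given relative to the deposited median. Genes that share reads with near copies (the AKR1C genes, CBR1 and CBR3, TRIM16 and TRIM16L, ferritins, histone genes, MT1L and ribosomal proteins) are uncertain, since Cufflinks may split their reads.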

Results

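The data are RNA sequencing tables of 12 libraries from H9-derived MSC, 2 from each of 6 groups. WT and AG cells were each sampled at early passage, at late passage and after transformation. The purpose, as far as the labels and series title state it, was to learn what a single-nucleotide recoding of NRF2 does to MSC as they age in culture and when they are transformed. The FPKM of a library summed to between 373308 and 502092, with 11580 to 12083 table lines at an FPKM of 1 or more. Effective fragments lay between 4.64 M and 7.44 M per library. Values are mean FPKM ± SD (n = 2 libraries), changes are log2 differences of log2(FPKM + 1), and positions are on hg19. RNA5-8S5, a ribosomal RNA, took 15.4% to 17.7% of the FPKM sum in the 4 late-passage libraries and 1.80% to 3.76% in the other 8.

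NFE2L2 itself (chromosome 2, 178095031 to 178129859) did not pass the test between genotypes in MSC. Its mRNA stood at 30.0 ± 0.35 FPKM in WT and 28.3 ± 0.57 in AG at early passage (log2 change -0.08, adjusted p = 0.44), and at 22.8 ± 1.4 and 22.1 ± 0.89 at late passage (-0.04, adjusted p = 0.63). In transformed cells it was lower in AG, at 23.7 ± 1.4 against 27.6 ± 0.44 (-0.21, adjusted p = 0.017). That call was lost without transformed WT replicate 1 (adjusted p = 0.081), WT replicate 2 (adjusted p = 0.051) or AG replicate 1 (adjusted p = 0.13), with 0.016 to 0.13 over its alternatives.

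At early passage, the 6 largest increases in AG over WT were those of AKR1C1, CBR1, HIST1H4A, AKR1C2, KYNU and MMP3. AKR1C1, an aldo-keto reductase that reduces steroids and reactive aldehydes (chromosome 10, 5005454 to 5020158), stood at 164 ± 3.6 against 2.15 ± 1.0 FPKM (log2 5.75, adjusted p = 6.2e-08). Its relative AKR1C2 stood at 10.6 ± 2.4 against 0.0661 ± 0.034 FPKM (log2 3.42, adjusted p = 5.9e-07), though reads of these genes may be shared with their near copies. CBR1, a carbonyl reductase (chromosome 21, 37442285 to 37445462), read 51.2 and 51.3 FPKM in AG and was listed at 0 in both WT libraries. KYNU, an enzyme of tryptophan breakdown, stood at 37.9 ± 0.44 against 2.79 ± 0.21 FPKM (log2 3.36, adjusted p = 1.5e-09).

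NRF2 target genes moved together at early passage. Among them, 34 of 36 were higher, 0 lower and 2 did not pass (34 and 0 adjusted over the list alone). NRF2 targets had a median of 0.99 (camera adjusted p = 1.3e-40, adjusted p = 0.0096 with an estimated correlation). NQO1, a quinone reductase, stood at 564 ± 17 against 276 ± 8.5 FPKM (log2 1.03, adjusted p = 2.9e-06). GCLM, a subunit of the enzyme that starts glutathione synthesis, was at 23.1 ± 1.2 against 15.2 ± 0.060 (0.58, adjusted p = 9.7e-04), and SLC7A11, the cystine importer, at 106 ± 5.2 against 43.7 ± 1.2 (1.26, adjusted p = 1.8e-07). TXNRD1, thioredoxin reductase, differed by 1.40 and the ferritin chain FTL, which has many pseudogenes, by 1.18 (adjusted p = 1.8e-07 and 6.6e-08). The members that did not pass were BLVRB (0.27, adjusted p = 0.17) and CBR3 (-0.13, adjusted p = 0.59). Without the 14 members that have near copies, 21 of 22 were still higher, with a median of 0.89.

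**Figure D1:**
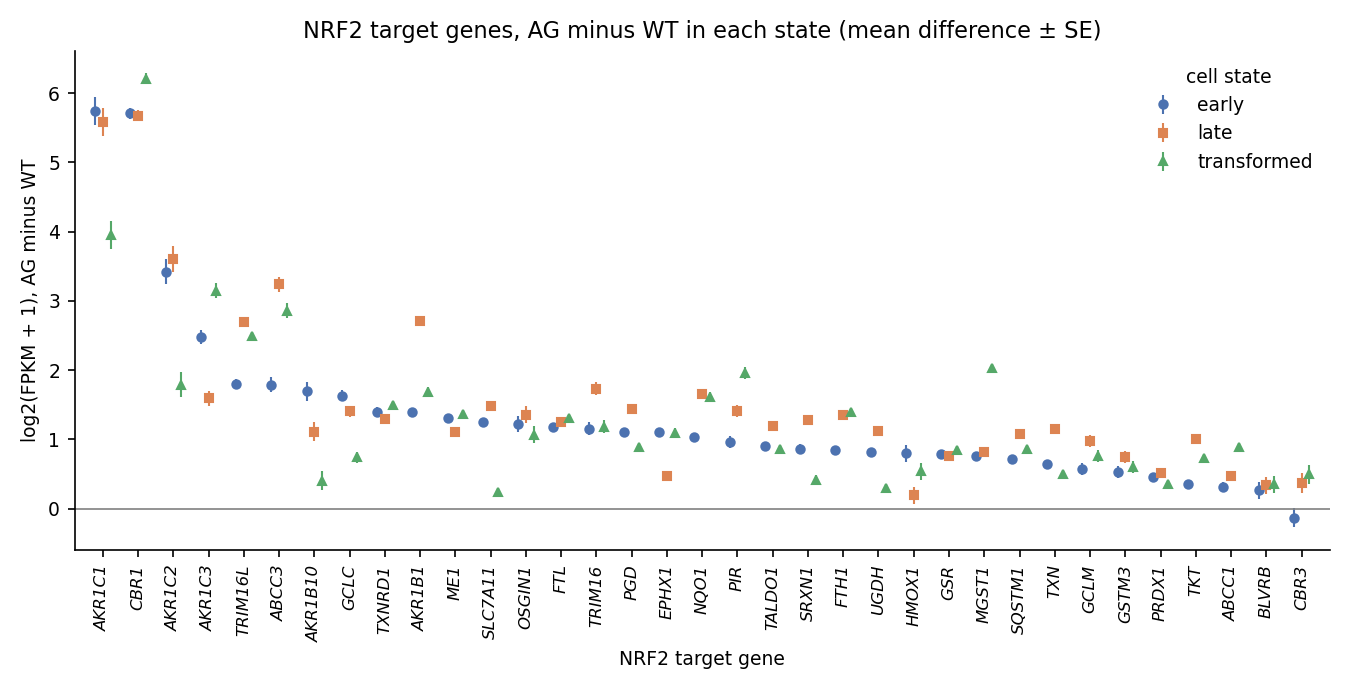
Log2 difference (AG minus WT, ± SE of the fit) of 35 of the 36 measured NRF2 target genes at early passage, late passage and after transformation, with genes sorted by the early-passage difference. Nearly every point lies over the line at 0, with medians over all 36 of 0.99, 1.22 and 0.98. CBR1 is listed at 0 in all WT libraries, so its points depend on the 1 added to each FPKM.

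HIST1H4A, a histone H4 gene with near copies, stood at 29.5 ± 1.7 against 1.78 ± 1.3 FPKM (log2 3.54, adjusted p = 3.4e-06), and MMP3, a matrix metalloproteinase, at 18.3 ± 2.2 against 0.908 ± 0.048 FPKM (log2 3.33, adjusted p = 3.7e-08). Lower in AG were HGF, a growth factor secreted by mesenchymal cells (1.74 ± 0.44 against 23.3 ± 0.21, -3.15, adjusted p = 1.9e-07), and IGFBP2, which binds insulin-like growth factors (6.66 ± 0.13 against 61.6 ± 0.38, -3.03, adjusted p = 1.9e-07). The imprinted genes MEST (10.3 ± 0.46 against 85.2 ± 8.3, -2.93, adjusted p = 5.6e-07) and DLK1 (0.295 ± 0.21 against 6.83 ± 1.6, -2.59, adjusted p = 2.6e-06) were also lower, as were the chemokine CCL2 (-2.60, adjusted p = 2.9e-06) and TRIM55, a muscle ubiquitin ligase (-2.06, adjusted p = 2.0e-07).

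Sugar metabolism genes were mostly higher in early-passage AG cells. In the glycolysis and hypoxia list, 17 of 28 were higher, 1 lower and 10 did not pass (18 and 1 adjusted over the list alone). Glycolysis genes had a median of 0.19 (camera adjusted p = 3.7e-06, adjusted p = 0.13 with an estimated correlation). LDHA, lactate dehydrogenase, was at 513 ± 0.93 against 290.1 ± 3.7, and the glucose transporter SLC2A1 at 34.2 ± 0.0023 against 24.4 ± 0.93. Immediate early genes, which respond to growth signals within minutes, were mostly lower: 2 of 18 were higher, 11 lower and 5 did not pass (2 and 12 adjusted over the list alone). Immediate early genes had a median of -0.43 (camera adjusted p = 3.9e-06, adjusted p = 0.13 with an estimated correlation). Examples were EGR1 (-0.91, adjusted p = 6.6e-05) and IER2 (-0.74, adjusted p = 2.7e-06). Epithelial keratins and claudins were lower, as 0 of 5 were higher, 4 lower and 1 did not pass (0 and 4 adjusted over the list alone). Epithelial markers had a median of -0.94 (camera adjusted p = 1.3e-05, adjusted p = 0.13 with an estimated correlation). KRT8 was at 61.2 ± 4.8 against 171 ± 15 and KRT18 at 57.5 ± 1.6 against 112 ± 8.2.

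Matrix genes at early passage went both ways, as 4 of 32 were higher, 14 lower and 14 did not pass (4 and 15 adjusted over the list alone). Their median was -0.22 (camera adjusted p = 1.3e-05, adjusted p = 0.43 with an estimated correlation). POSTN, periostin, was higher (15.9 ± 4.4 against 2.02 ± 0.78, 2.49, adjusted p = 4.6e-06), and COL11A1 (-1.51, adjusted p = 1.0e-05) and BGN, biglycan (-0.47, adjusted p = 2.9e-05), were lower. For mitosis genes, 5 of 30 were higher, 0 lower and 25 did not pass (11 and 0 adjusted over the list alone). Their median was 0.19 (camera adjusted p = 1.0e-04, adjusted p = 0.43 with an estimated correlation). Of HOX genes, which mark body position, 4 of 10 were higher, 0 lower and 6 did not pass (4 and 0 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 0.0096, adjusted p = 0.13 with an estimated correlation). Only 2 reached the filter without AG, so it partly set the direction.

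In limma's test of early-passage AG against WT, 2026 of 12430 genes changed, 1199 higher and 827 lower in AG, and 221 of them by at least 2-fold. The count was 1092 in a fit of these groups alone, 1232 without AG replicate 1 and 1237 without AG replicate 2. With median-ratio scaling 1025 were higher and 1000 lower, and with quantile normalization 1012 and 1069.

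At late passage, the 6 largest increases in AG over WT were those of CBR1, AKR1C1, G0S2, KYNU, HIST1H4A and IL1B. G0S2, an inhibitor of fat breakdown, was at 96.7 ± 9.8 against 2.98 ± 0.98 FPKM (log2 4.64, adjusted p = 7.3e-09), and IL1B, an inflammatory cytokine (chromosome 2, 113587337 to 113594356), at 40.5 ± 2.7 against 1.13 ± 0.22 FPKM (log2 4.29, adjusted p = 5.9e-10). KYNU was at 52.0 ± 4.7 against 1.17 ± 0.058 FPKM (log2 4.61, adjusted p = 8.6e-11), and AKR1C1 at 220.5 ± 9.3 against 3.62 ± 0.28 FPKM (log2 5.58, adjusted p = 1.2e-08). CBR1 read 48.2 and 52.1 in AG and HIST1H4A 24.0 and 19.9, and both were listed at 0 in both WT libraries. Lower in AG were IGFBP2 (1.93 ± 0.56 against 119 ± 8.6, -5.37, adjusted p = 1.3e-09) and MEST (2.16 ± 0.52 against 79.4 ± 3.2, -4.68, adjusted p = 7.0e-09). PTGIS, prostacyclin synthase, stood at 0.0104 ± 0.015 against 24.8 ± 0.065 FPKM (log2 -4.67, adjusted p = 5.9e-10), and TRIM55 at 0.397 ± 0.063 against 23.5 ± 0.24 FPKM (log2 -4.13, adjusted p = 7.3e-10). SCG2, a secretory granule protein (-3.51, adjusted p = 5.9e-10), and NTN4, a netrin (-3.47, adjusted p = 8.6e-10), were lower too.

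NRF2 targets at late passage were again mostly higher in AG, as 34 of 36 were higher, 0 lower and 2 did not pass (35 and 0 adjusted over the list alone). NRF2 targets had a median of 1.22 (camera adjusted p = 1.1e-21, adjusted p = 0.053 with an estimated correlation). AKR1B1, an aldose reductase, was at 961 ± 52 against 146 ± 5.6 FPKM (log2 2.71, adjusted p = 5.9e-10), and PGD, which makes NADPH, at 309 ± 0.46 against 114 ± 0.22 FPKM (log2 1.43, adjusted p = 5.4e-09). NQO1 was at 406 ± 5.6 against 129 ± 15 (1.66, adjusted p = 2.4e-08). HMOX1, heme oxygenase, did not pass, at 8.09 ± 2.1 against 6.84 ± 0.16 (0.19, adjusted p = 0.23), nor did CBR3 (0.37, adjusted p = 0.053). Without members that have near copies, 21 of 22 were higher, with a median of 1.11.

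Proliferation genes were higher in late-passage AG cells than in late-passage WT cells. For mitosis, 30 of 30 were higher, 0 lower and 0 did not pass (30 and 0 adjusted over the list alone). Mitosis genes had a median of 1.62 (camera adjusted p = 1.1e-21, adjusted p = 0.068 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, was at 33.4 ± 0.69 against 8.17 ± 0.39, CCNB1, cyclin B1, at 37.0 ± 0.50 against 12.6 ± 0.70, and BIRC5, survivin, at 21.1 ± 0.65 against 6.15 ± 0.024. For DNA replication, 29 of 31 were higher, 0 lower and 2 did not pass (29 and 0 adjusted over the list alone), with the helicase subunit MCM7 at 32.6 ± 1.3 against 13.7 ± 0.28 and the ribonucleotide reductase subunit RRM2 at 33.4 ± 0.32 against 10.6 ± 0.41. Replication genes had a median of 1.03 (camera adjusted p = 2.7e-14, adjusted p = 0.1 with an estimated correlation). In the nuclear lamina and heterochromatin list, 20 of 24 were higher, 0 lower and 4 did not pass (21 and 0 adjusted over the list alone), with LMNB1, lamin B1, at 18.9 ± 1.6 against 4.42 ± 0.18. Lamina genes had a median of 0.64 (camera adjusted p = 1.8e-08, adjusted p = 0.068 with an estimated correlation).

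Secreted factors of senescent cells were mostly higher in late AG, as 27 of 35 were higher, 7 lower and 1 did not pass (27 and 7 adjusted over the list alone). Secreted factors had a median of 1.10 (camera adjusted p = 5.3e-06, adjusted p = 0.13 with an estimated correlation). EREG, an epidermal growth factor ligand, was at 46.1 ± 1.3 against 4.17 ± 0.14 FPKM (log2 3.19, adjusted p = 1.3e-09), IL8, a neutrophil chemokine, at 245 ± 14 against 55.5 ± 4.8, and IGFBP7 at 599.7 ± 5.1 against 1633 ± 102. In cholesterol synthesis, 21 of 23 were higher, 0 lower and 2 did not pass (21 and 0 adjusted over the list alone), with INSIG1 at 20.02 ± 0.19 against 5.73 ± 0.091 and ACAT2 at 39.4 ± 1.8 against 18.6 ± 0.52. Cholesterol genes had a median of 0.72 (camera adjusted p = 2.2e-09, adjusted p = 0.12 with an estimated correlation). Contractile genes were mostly lower, as 4 of 17 were higher, 9 lower and 4 did not pass (4 and 10 adjusted over the list alone), with ACTA2, smooth muscle actin, at 18.9 ± 0.43 against 47.9 ± 4.9. Contractile genes had a median of -0.20 (camera adjusted p = 0.003, adjusted p = 0.42 with an estimated correlation).

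MSC surface markers at late passage went both ways, as 7 of 17 were higher, 6 lower and 4 did not pass (7 and 6 adjusted over the list alone). Surface markers had a median of -0.04, a mean of 0.12 and camera direction down (camera adjusted p = 0.63). Fry gave adjusted p = 0.0023. ANPEP, aminopeptidase N, was at 52.7 ± 0.97 against 13.01 ± 0.24 FPKM (log2 1.94, adjusted p = 2.2e-09), and THY1 at 19.2 ± 0.26 against 33.3 ± 0.52 FPKM (log2 -0.76, adjusted p = 4.2e-06). Epithelial markers were lower in part at late passage, as 0 of 5 were higher, 3 lower and 2 did not pass (0 and 3 adjusted over the list alone). Epithelial markers had a median of -1.86 (camera adjusted p = 0.001, adjusted p = 0.17 with an estimated correlation). Both measured skeletal muscle markers were higher, TNNT1 by 0.82 and PAX3 by 1.21, with a camera adjusted p = 0.081 for the pair. Limma called 5303 genes between the genotypes at late passage, 3533 higher and 1770 lower in AG, and 732 of them by at least 2-fold. With median-ratio scaling 5261 changed, 2677 higher and 2584 lower, and with quantile normalization 2539 were higher and 2617 lower.

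The largest increases in transformed AG over WT cells included genes that were listed at 0 in the WT line. S100A6, a calcium-binding protein (chromosome 1, 153507076 to 153508717), read 407 and 389 FPKM in the AG libraries and was listed at 0 in both WT libraries. CBR1 (69.3 and 76.9), IL24, a cytokine (54.95 and 46.9), and MT1L, a metallothionein gene with near copies (35.7 and 21.2), were also listed at 0 in both transformed WT libraries. IGFBP5 stood at 285 ± 4.7 against 8.42 ± 0.86 FPKM (log2 4.93, adjusted p = 5.1e-12), and TNFRSF11B, the decoy receptor osteoprotegerin, at 56.8 ± 2.9 against 1.10 ± 0.31 FPKM (log2 4.79, adjusted p = 7.8e-10). Lower in AG were CLEC2B, a lectin (1.64 ± 0.49 against 54.2 ± 2.2, -4.40, adjusted p = 3.9e-09), RGS4, a regulator of G protein signalling (5.37 ± 0.48 against 115 ± 0.89, -4.19, adjusted p = 1.5e-09), and ABI3BP, a matrix protein (2.47 ± 0.043 against 45.5 ± 4.2, -3.74, adjusted p = 1.5e-09). FAM84B (-3.58, adjusted p = 2.7e-09), the transcription factor ZIC2 (-3.44, adjusted p = 9.0e-09) and KRT8 (-3.30, adjusted p = 1.2e-09) were lower as well.

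**Figure D2:**
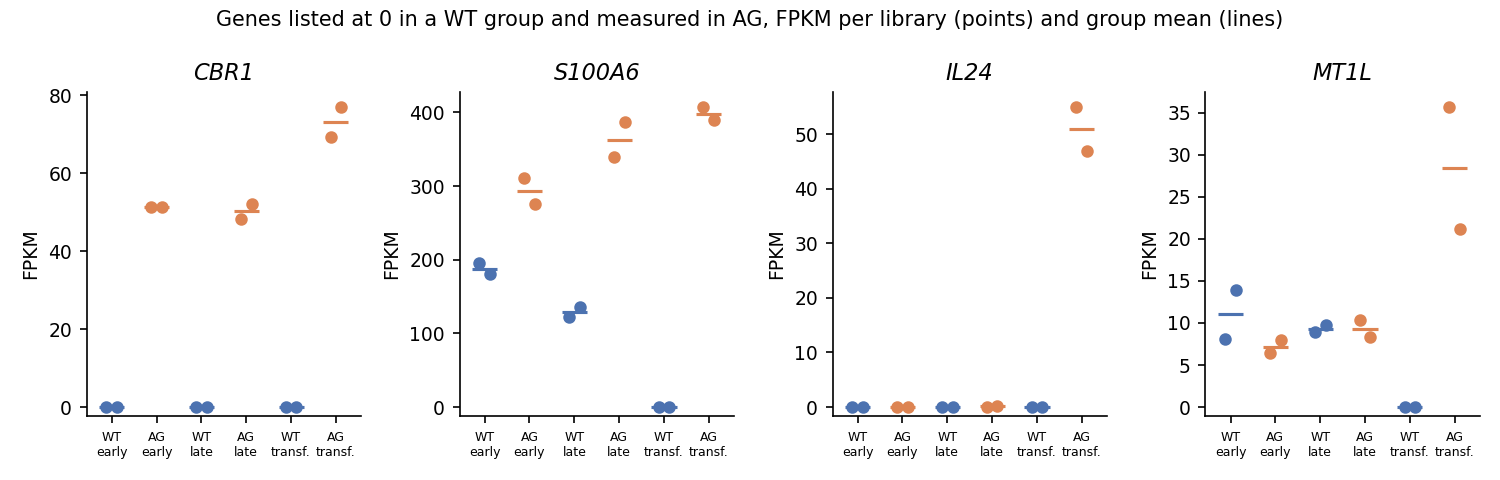
FPKM of CBR1, S100A6, IL24 and MT1L in each of the 12 libraries, by group. CBR1 is listed at 0 in all 6 WT libraries and S100A6 in both transformed WT libraries, against 407 and 389 in transformed AG.

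NRF2 targets were higher in transformed AG cells as well, where 36 of 36 were higher, 0 lower and 0 did not pass (36 and 0 adjusted over the list alone). NRF2 targets had a median of 0.98 (camera adjusted p = 1.2e-21, adjusted p = 0.026 with an estimated correlation). MGST1, a microsomal glutathione transferase, was at 199.9 ± 5.5 against 48.2 ± 3.0 FPKM (log2 2.03, adjusted p = 2.7e-09), and NQO1 at 309.7 ± 0.71 against 100.4 ± 5.2 (1.62, adjusted p = 2.5e-08). SLC7A11 differed least among the targets named here, by 0.24 (adjusted p = 0.0057), and HMOX1 by 0.54 (adjusted p = 0.005). Without members that have near copies, 22 of 22 were higher, with a median of 0.88.

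Position and lineage genes differed between the transformed lines. Of 31 listed HOX genes 10 were tested, and 5 of these reached the filter only through transformed AG, so their direction was partly set by it. In the full list 10 of 10 were higher, 0 lower and 0 did not pass (10 and 0 adjusted over the list alone). HOX genes had a median of 1.24 (camera adjusted p = 5.0e-07, adjusted p = 0.026 with an estimated correlation). The other 5 were all higher, with a median of 2.18 (camera adjusted p = 8.9e-05, adjusted p = 0.025 with an estimated correlation, over 2 tests added after seeing the data). Only 2 of the 10 reached the filter without any AG library, so it partly set the direction of these 5 too. HOXB3 was at 5.75 ± 0.61 against 0.2001 ± 0.039, low levels. Neural markers were mostly higher, as 4 of 6 were higher, 0 lower and 2 did not pass (4 and 1 adjusted over the list alone), with the adhesion molecules L1CAM at 15.99 ± 0.53 against 0.231 ± 0.096 and NCAM1 at 4.70 ± 0.28 against 0.0204 ± 0.0049. Neural markers had a median of 1.63 (camera adjusted p = 0.004, adjusted p = 0.098 with an estimated correlation). Osteogenic and chondrogenic genes gave these counts: 6 of 10 were higher, 0 lower and 4 did not pass (6 and 0 adjusted over the list alone), with RUNX2, a regulator of bone formation, at 4.64 ± 0.030 against 1.69 ± 0.033. Osteogenic genes had a median of 0.50 (camera adjusted p = 0.0097, adjusted p = 0.17 with an estimated correlation). In the adipogenic list, 5 of 8 were higher, 1 lower and 2 did not pass (5 and 1 adjusted over the list alone), with CEBPD at 12.6 ± 1.3 against 3.30 ± 0.074. Adipogenic genes had a median of 0.81 (camera adjusted p = 0.04, adjusted p = 0.19 with an estimated correlation). Among haematopoietic markers, 1 of 3 were higher, 0 lower and 2 did not pass (1 and 0 adjusted over the list alone), with LCP1 at 1.61. Haematopoietic markers had a median of 0.18 (camera adjusted p = 0.17). Among pluripotent cell markers, 2 of 4 were higher, 0 lower and 2 did not pass (2 and 0 adjusted over the list alone). Pluripotent markers had a median of 0.16 (camera adjusted p = 0.69).

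Stress and metabolism lists split in direction between the transformed lines. Glycolysis and hypoxia genes were higher, as 22 of 28 were higher, 0 lower and 6 did not pass (22 and 0 adjusted over the list alone), with LDHA at 688 ± 17 against 308 ± 3.3 and VEGFA at 79.5 ± 3.8 against 37.1 ± 0.71. Glycolysis genes had a median of 0.32 (camera adjusted p = 4.8e-08, adjusted p = 0.081 with an estimated correlation). Heat shock genes were lower, as 0 of 14 were higher, 11 lower and 3 did not pass (0 and 12 adjusted over the list alone), with the chaperones HSPA8 at 478 ± 7.4 against 738 ± 13 and HSPD1 at 197 ± 4.0 against 271 ± 5.9. Heat shock genes had a median of -0.38 (camera adjusted p = 3.4e-06, adjusted p = 0.21 with an estimated correlation). DNA replication genes were lower in part, as 0 of 31 were higher, 15 lower and 16 did not pass (0 and 15 adjusted over the list alone), with CDC6 at 25.1 ± 1.0 against 35.1 ± 1.4. Replication genes had a median of -0.22 (camera adjusted p = 5.6e-04, adjusted p = 0.46 with an estimated correlation). For mitosis genes, 3 of 30 were higher, 4 lower and 23 did not pass (2 and 4 adjusted over the list alone). Mitosis genes had a median of 0.02, a mean of -0.01 and camera direction down (camera adjusted p = 0.69). Matrix genes went both ways, as 11 of 32 were higher, 15 lower and 6 did not pass (11 and 15 adjusted over the list alone), with COL6A3 at 125 ± 0.15 against 9.22 ± 0.27 and LOX, which crosslinks collagen, at 38.7 ± 0.56 against 161 ± 0.29. Matrix genes had a median of -0.15, a mean of 0.21 and camera direction down (camera adjusted p = 0.6).

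Between the transformed lines limma called 5725 genes, 2998 higher and 2727 lower in AG, and 705 of them by at least 2-fold, 548 of these higher. With quantile normalization 2607 were higher and 3231 lower. HRAS mRNA also differed between the lines and is given with the change on transformation.

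Genotype calls were shared across states in numbers that can be set beside the product of their shares. At early and late passage alike, 894 genes were higher and 511 lower in AG, where 341 and 118 were expected by that product, and 115 changed in opposite directions (406 expected). In all 3 states, 435 were higher and 147 lower (393 and 177 with median-ratio scaling, 358 and 233 with quantile normalization), where 82.2 and 25.8 were expected, and 439 were called in every state with mixed directions (290 expected). Between early passage and transformed cells 539 were higher and 230 lower in both (289 and 181 expected), and 542 went opposite ways (463 expected). Between late passage and transformed cells these were 1094 and 425 (852 and 388 expected), with 1384 opposite (1202 expected). No library was in more than 1 of these comparisons, but the labels do not give the number of clones per genotype.

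Late passage of WT cells was marked by a fall of cell division genes. Of the mitosis genes, 0 of 30 rose, 30 fell and 0 did not pass (0 and 30 adjusted over the list alone). Mitosis genes moved by a median of -2.82, or -2.71 less the median of all genes (camera adjusted p = 1.9e-18, adjusted p = 0.11 with an estimated correlation). DLGAP5, a spindle protein, went from 42.8 ± 1.2 to 3.47 ± 1.1 FPKM (-3.31, adjusted p = 2.1e-08), NUF2, a kinetochore protein, from 30.9 ± 0.43 to 2.27 ± 0.16 (-3.29, adjusted p = 1.7e-10), and PTTG1, securin, from 228 ± 19.7 to 22.7 ± 0.97 (-3.27, adjusted p = 9.1e-10). HMGB2, a chromatin protein (-3.27, adjusted p = 2.3e-10), and ASPM, a spindle pole protein (-3.26, adjusted p = 2.0e-10), fell too. The histone gene H3F3A, which has pseudogene copies, fell by 3.67 with widely spread early libraries (20.9 and 6.47), and lost its call without early WT replicate 1 (adjusted p = 0.065, with 0.0021 to 0.065 over its alternatives). Increases were led by ICAM1, an adhesion molecule of inflamed cells (19.6 ± 0.57 against 0.614 ± 0.095, 3.67, adjusted p = 2.0e-10), and DHRS3, a retinal reductase (18.2 ± 1.6 against 0.710 ± 0.021, 3.49, adjusted p = 2.4e-10). Higher too were CCL2 (3.40, adjusted p = 4.7e-08), the sulfatase SULF1 (3.203, adjusted p = 1.1e-08), POSTN (3.08, adjusted p = 1.2e-07) and F3, tissue factor (2.91, adjusted p = 1.7e-10). NFE2L2 fell from 30.0 ± 0.35 to 22.8 ± 1.4 (-0.38, adjusted p = 2.7e-04).

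Other groups moved with passage in WT cells. In DNA replication, 0 of 31 rose, 30 fell and 1 did not pass (0 and 30 adjusted over the list alone), with RRM2 from 64.4 ± 6.9 to 10.6 ± 0.41. Replication genes moved by a median of -1.79, or -1.68 less the median of all genes (camera adjusted p = 1.3e-13, adjusted p = 0.11 with an estimated correlation). In the lamina and heterochromatin list, 0 of 24 rose, 22 fell and 2 did not pass (0 and 22 adjusted over the list alone), with LMNB1 from 48.6 ± 0.44 to 4.42 ± 0.18 and EZH2, a histone methyltransferase, from 14.4 ± 0.85 to 2.19 ± 0.22. Lamina genes moved by a median of -1.08, or -0.97 less the median of all genes (camera adjusted p = 2.3e-08, adjusted p = 0.11 with an estimated correlation). Matrix genes rose, as 25 of 32 rose, 0 fell and 7 did not pass (25 and 0 adjusted over the list alone), with THBS1, thrombospondin, from 117 ± 3.3 to 569 ± 63 and LOX from 46.7 ± 1.2 to 147 ± 6.8. Matrix genes moved by a median of 0.89, or 1.00 less the median of all genes (camera adjusted p = 3.0e-11, adjusted p = 0.19 with an estimated correlation). Contractile genes did too, as 13 of 17 rose, 0 fell and 4 did not pass (13 and 0 adjusted over the list alone), with MYL9 from 198 ± 14 to 617 ± 1.5. Contractile genes moved by a median of 0.54, or 0.65 less the median of all genes (camera adjusted p = 3.9e-07, adjusted p = 0.14 with an estimated correlation). TGF-beta and YAP targets mostly rose, as 16 of 19 rose, 3 fell and 0 did not pass (16 and 3 adjusted over the list alone), with CTGF from 65.5 ± 1.5 to 307 ± 16. TGF-beta targets moved by a median of 0.87, or 0.98 less the median of all genes (camera adjusted p = 9.3e-07, adjusted p = 0.11 with an estimated correlation). Secreted factors of senescent cells mostly rose, as 22 of 35 rose, 3 fell and 10 did not pass (23 and 4 adjusted over the list alone), with IGFBP7 from 334 ± 24 to 1633 ± 102 and PLAU, urokinase, from 95.5 ± 5.7 to 327 ± 16. Secreted factors moved by a median of 0.50, or 0.61 less the median of all genes (camera adjusted p = 3.7e-07, adjusted p = 0.12 with an estimated correlation).

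Interferon response genes in late WT cells rose in part, as 7 of 16 rose, 0 fell and 9 did not pass (5 and 0 adjusted over the list alone). Interferon genes moved by a median of 0.17, or 0.28 less the median of all genes (camera adjusted p = 0.036, adjusted p = 0.38 with an estimated correlation). That call was lost with median-ratio scaling (adjusted p = 0.073). Among ribosomal protein genes, 17 of 34 rose, 6 fell and 11 did not pass (17 and 6 adjusted over the list alone). Ribosomal proteins moved by a median of 0.08, or 0.20 less the median of all genes (camera adjusted p = 0.0086, adjusted p = 0.55 with an estimated correlation). Proteasome subunits mostly fell, as 2 of 26 rose, 19 fell and 5 did not pass (2 and 19 adjusted over the list alone), with PSMA3 from 89.1 ± 3.0 to 57.4 ± 1.9. Proteasome subunits moved by a median of -0.37, or -0.26 less the median of all genes (camera adjusted p = 0.0048, adjusted p = 0.55 with an estimated correlation). NRF2 targets went both ways, as 12 of 36 rose, 13 fell and 11 did not pass (12 and 13 adjusted over the list alone), with NQO1 from 276 ± 8.5 to 129 ± 15 and FTL from 1593 ± 85 to 2489 ± 78. NRF2 targets moved by a median of -0.07, or 0.04 less the median of all genes, a mean of -0.08 and camera direction up (camera adjusted p = 0.93). Its median lay between -0.24 and 0.02 over the alternatives. With passage in WT, limma called 8051 genes, 3119 higher and 4932 lower at late passage, and 1242 by at least 2-fold. With median-ratio scaling 7972 changed, 4122 higher and 3850 lower. All late libraries also carried the raised share of RNA5-8S5.

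**Figure D3:**
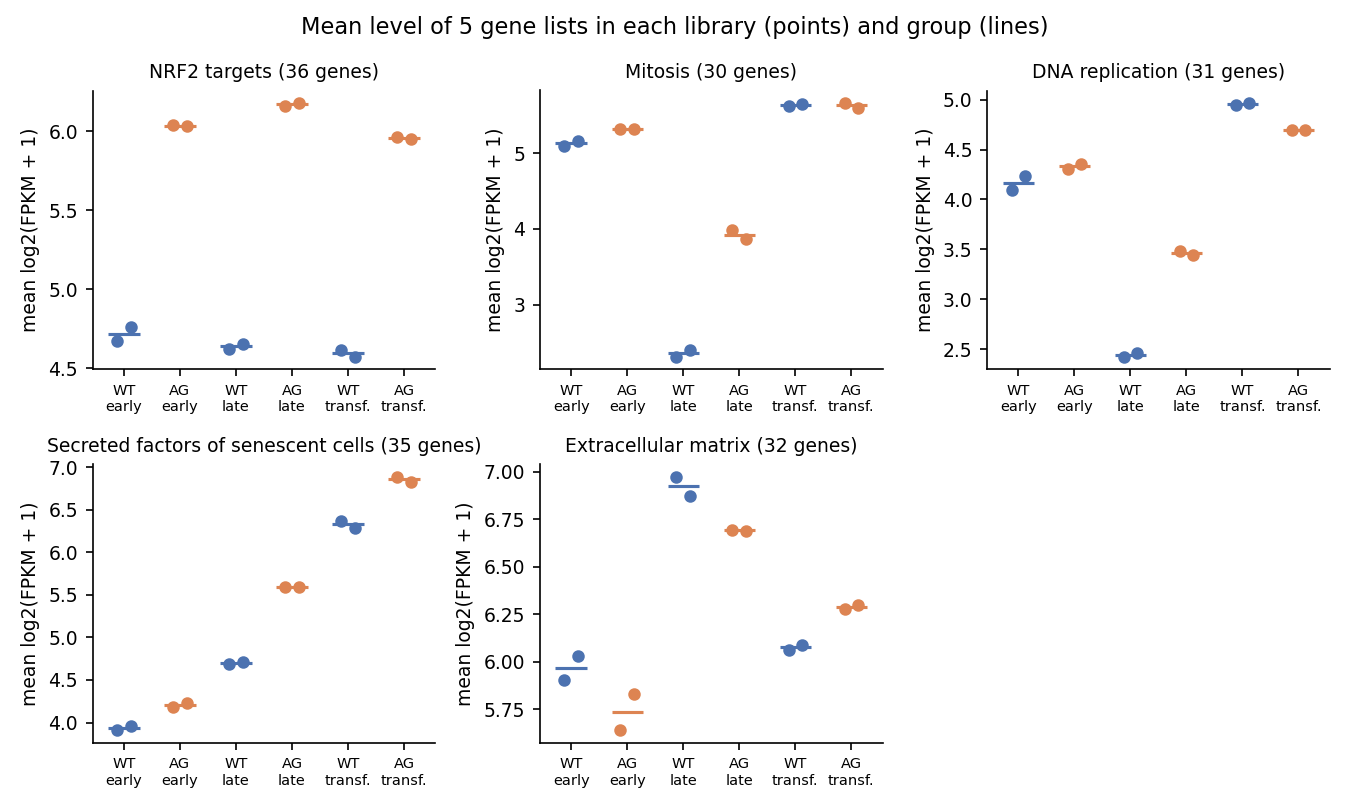
Mean log2(FPKM + 1) of 5 gene lists (NRF2 targets, mitosis, DNA replication, secreted factors of senescent cells, extracellular matrix) in each of the 12 libraries, by group. Mitosis genes lie lowest in late-passage WT, and NRF2 targets lie higher in AG than in WT in each state.

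In AG cells, the largest increases with passage included those of cytokine genes. IL6 went from 0.363 ± 0.063 to 26.2 ± 3.1 FPKM (4.31, adjusted p = 4.0e-09), and IL1B from 2.50 ± 0.073 to 40.5 ± 2.7 (3.57, adjusted p = 3.1e-09). ICAM1 went from 2.31 ± 0.30 to 43.2 ± 3.2 (3.74, adjusted p = 1.1e-09) and CCL2 from 2.51 ± 1.1 to 37.7 ± 1.2 (3.50, adjusted p = 1.1e-07). The cytokine IL32 (3.35, adjusted p = 1.5e-07) and HSD11B1, which activates cortisol (3.202, adjusted p = 2.2e-07), rose as well. FOS, an immediate early transcription factor, fell from 30.6 ± 4.6 to 2.49 ± 0.29 (-3.17, adjusted p = 7.4e-08), and CD24, a surface glycoprotein, from 23.4 ± 1.2 to 2.18 ± 0.12 (-2.94, adjusted p = 2.4e-08). ANXA10 (-2.14), HIST1H2BM (-2.09), MTRNR2L8 (-2.08) and RGS4 (-2.06) also fell (adjusted p = 1.3e-06, 2.3e-04, 1.1e-07 and 2.2e-07). NFE2L2 fell by 0.35 (adjusted p = 7.4e-04).

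Several lists that moved with passage in WT were also called in AG. In the secreted factor list, 32 of 35 rose, 1 fell and 2 did not pass (32 and 2 adjusted over the list alone). Secreted factors moved by a median of 1.10 (camera adjusted p = 7.8e-17, adjusted p = 0.086 with an estimated correlation). For mitosis, 0 of 30 rose, 30 fell and 0 did not pass (0 and 30 adjusted over the list alone), with CCNB1 from 91.2 ± 1.1 to 37.0 ± 0.50. Mitosis genes moved by a median of -1.44 (camera adjusted p = 5.9e-17, adjusted p = 0.15 with an estimated correlation). For DNA replication, 0 of 31 rose, 30 fell and 1 did not pass (0 and 30 adjusted over the list alone). Replication genes moved by a median of -0.90 (camera adjusted p = 1.9e-11, adjusted p = 0.16 with an estimated correlation). Among matrix genes, 27 of 32 rose, 1 fell and 4 did not pass (27 and 1 adjusted over the list alone), with COL6A1 from 369 ± 35 to 1221 ± 84. Matrix genes moved by a median of 0.99 (camera adjusted p = 2.3e-13, adjusted p = 0.16 with an estimated correlation). Contractile genes rose, as 17 of 17 rose, 0 fell and 0 did not pass (17 and 0 adjusted over the list alone). Contractile genes moved by a median of 0.61 (camera adjusted p = 1.6e-09, adjusted p = 0.15 with an estimated correlation). Of TGF-beta and YAP targets in AG, 15 of 19 rose, 2 fell and 2 did not pass (15 and 2 adjusted over the list alone). TGF-beta targets moved by a median of 0.69 (camera adjusted p = 9.1e-07, adjusted p = 0.15 with an estimated correlation). In the lamina list, 0 of 24 rose, 16 fell and 8 did not pass (0 and 16 adjusted over the list alone). Lamina genes moved by a median of -0.49 (camera adjusted p = 5.4e-05, adjusted p = 0.16 with an estimated correlation).

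Interferon response genes rose in part in late AG cells too, where 9 of 16 rose, 1 fell and 6 did not pass (9 and 1 adjusted over the list alone), with IRF1 from 5.08 ± 0.21 to 15.7 ± 0.52. Interferon genes moved by a median of 0.40 (camera adjusted p = 0.0024, adjusted p = 0.19 with an estimated correlation). The passage interaction of this list did not pass (camera adjusted p = 0.52). Of the NRF2 targets, 13 of 36 rose, 11 fell and 12 did not pass (13 and 11 adjusted over the list alone), and AKR1B1 went from 229.7 ± 17 to 961 ± 52. NRF2 targets moved by a median of 0.07 (camera adjusted p = 0.24). Its median lay between -0.11 and 0.15 over the alternatives. Passage in AG gave 7198 called genes in limma, 3037 higher and 4161 lower, and 638 by at least 2-fold. With median-ratio scaling 3685 were higher and 3498 lower.

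Passage changes could be compared between the genotypes by their interaction. Mitosis genes fell less in AG than in WT, as 30 of 30 were above 0, 0 below 0 and 0 did not pass (30 and 0 adjusted over the list alone). Mitosis genes gave a median interaction of 1.46 (camera adjusted p = 4.9e-31, adjusted p = 0.065 with an estimated correlation). The median change was -2.82 in WT and -1.44 in AG, with a 95% bootstrap interval of the interaction from 1.33 to 1.56. DLGAP5 (1.56, adjusted p = 5.4e-04), BIRC5 (1.60, adjusted p = 1.3e-06) and PLK1, a mitotic kinase (1.54, adjusted p = 1.8e-06), were among them. Among DNA replication genes, 26 of 31 were above 0, 0 below 0 and 5 did not pass (29 and 0 adjusted over the list alone). Replication genes gave a median interaction of 0.93 (camera adjusted p = 9.2e-18, adjusted p = 0.1 with an estimated correlation). Among lamina and heterochromatin genes, 17 of 24 were above 0, 0 below 0 and 7 did not pass (17 and 0 adjusted over the list alone), with LMNB1 at 1.77 (adjusted p = 1.8e-06). Lamina genes gave a median interaction of 0.60 (camera adjusted p = 4.8e-11, adjusted p = 0.065 with an estimated correlation). For secreted factors of senescent cells, 19 of 35 were above 0, 4 below 0 and 12 did not pass (22 and 4 adjusted over the list alone), led by IL1B (2.74, adjusted p = 1.6e-06) and the chemokine CXCL1 (1.83, adjusted p = 5.3e-06). Secreted factors gave a median interaction of 0.62 (camera adjusted p = 4.6e-06, adjusted p = 0.14 with an estimated correlation). Matrix genes did not pass as a list, as 8 of 32 were above 0, 10 below 0 and 14 did not pass (8 and 13 adjusted over the list alone), with a 95% interval of the median from -0.34 to 0.28. Matrix genes gave a median interaction of -0.06, a mean of 0.00 and camera direction down (camera adjusted p = 0.13).

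In cholesterol synthesis, 16 of 23 were above 0, 0 below 0 and 7 did not pass (19 and 0 adjusted over the list alone). Cholesterol genes gave a median interaction of 0.50 (camera adjusted p = 1.8e-09, adjusted p = 0.14 with an estimated correlation). Of the NRF2 targets, 16 of 36 were above 0, 3 below 0 and 17 did not pass (18 and 4 adjusted over the list alone), with AKR1B1 at 1.32 (adjusted p = 5.3e-06). NRF2 targets gave a median interaction of 0.22 (camera adjusted p = 0.01, adjusted p = 0.32 with an estimated correlation).

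Single genes with the largest passage interactions were HSD11B1, listed at 0 in both early WT libraries, with 12.8 and 14.8 FPKM in late AG and 0 and 0.0843 in late WT (adjusted p = 1.8e-05), and G0S2, with 96.7 ± 9.8 and 2.98 ± 0.98 (3.14, adjusted p = 8.2e-06). MSC, a transcription factor also called musculin, read 13.9 and 15.3 in late AG, 0.224 and 0.111 in late WT and was listed at 0 in both early WT libraries (adjusted p = 9.5e-06). DHRS3 rose in WT and stood at 0.819 ± 0.066 in late AG against 18.2 ± 1.6 in late WT (-3.49, adjusted p = 1.3e-07). PTGIS had a negative interaction too (-2.58, adjusted p = 2.5e-06). NUPR1, a stress-response protein, read 5.04 and 6.13 in late WT and was listed at 0 in both early WT libraries (adjusted p = 2.2e-04), and LBH had an interaction of -2.38 (adjusted p = 1.9e-05).

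By limma, 2304 genes had a passage interaction, 1518 above 0 and 786 below, and with median-ratio scaling 2438 did, 1276 above 0 and 1162 below. Passage calls overlapped between the genotypes, with 2219 genes higher in both, 3521 lower in both (762 and 1651 expected) and 203 in opposite directions. Among the 8051 genes called in WT, the slope of the AG change on the WT change across genes was 0.631 (r 0.835, rho 0.846), and genes are not independent replicates. With no genotype effect, simulations gave a slope of 0.945 (SD 0.018 over 100 runs). The median change of the 3119 genes that rose in WT was 0.55 in WT and 0.40 in AG, and of the 4932 that fell -0.55 and -0.39. The reverse slope, WT on AG among the genes called in AG, was 0.986, against 0.941 simulated.

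**Figure D4:**
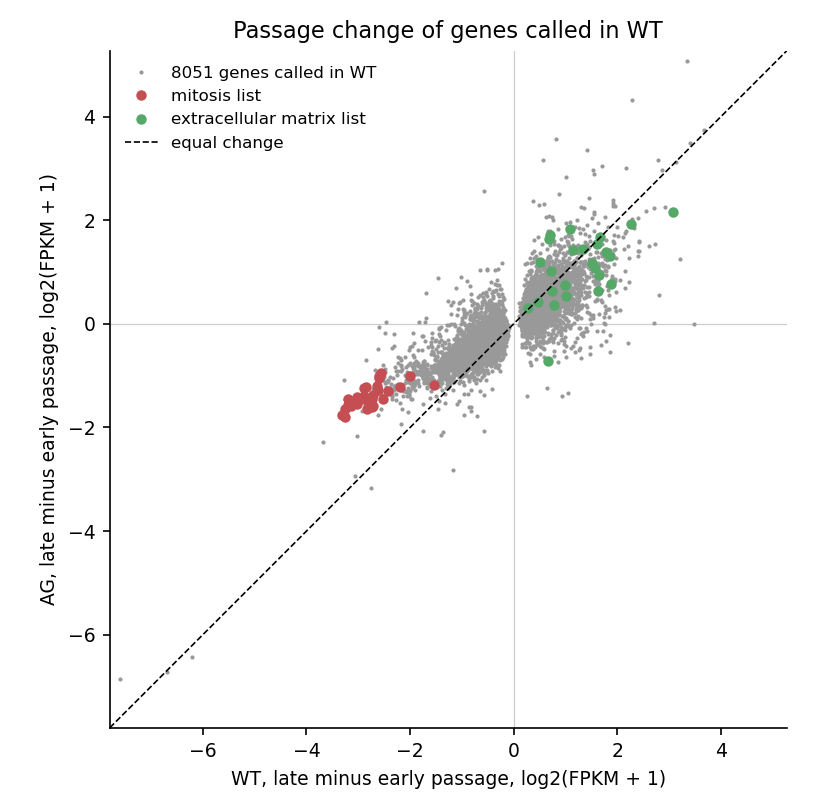
Log2 change from early to late passage in AG (y axis) against WT (x axis) for the 8051 genes called in WT, with mitosis genes in red, matrix genes in green and the line of equal change dashed. Mitosis genes lie above the line, with medians of -2.82 in WT and -1.44 in AG.

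Transformed WT cells differed from early-passage WT MSC in the transduced genes. TERT (chromosome 5, 1253287 to 1295162) was listed at 0 in all 8 MSC libraries and read 189 and 198 FPKM in transformed WT and 185 and 185 in transformed AG. HRAS went from 32.6 ± 4.1 to 224 ± 16 in WT (2.75, adjusted p = 1.7e-09) and from 29.5 ± 1.2 to 119 ± 7.7 in AG (1.98, adjusted p = 3.9e-08), and the table does not part the transduced HRAS from the cell's own. Between the transformed lines, HRAS was lower in AG (-0.91, adjusted p = 1.9e-05), while TERT did not pass (-0.07, adjusted p = 0.45). The interaction of HRAS passed (-0.78, adjusted p = 0.001). NFE2L2 did not pass in WT (-0.12, adjusted p = 0.13), though it did with median-ratio scaling (-0.25) or quantile normalization (-0.35), and fell by 0.25 in AG (adjusted p = 0.0055), a call lost without transformed AG replicate 1 (adjusted p = 0.057, with 1.6e-04 to 0.057 over its alternatives).

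**Figure D5:**
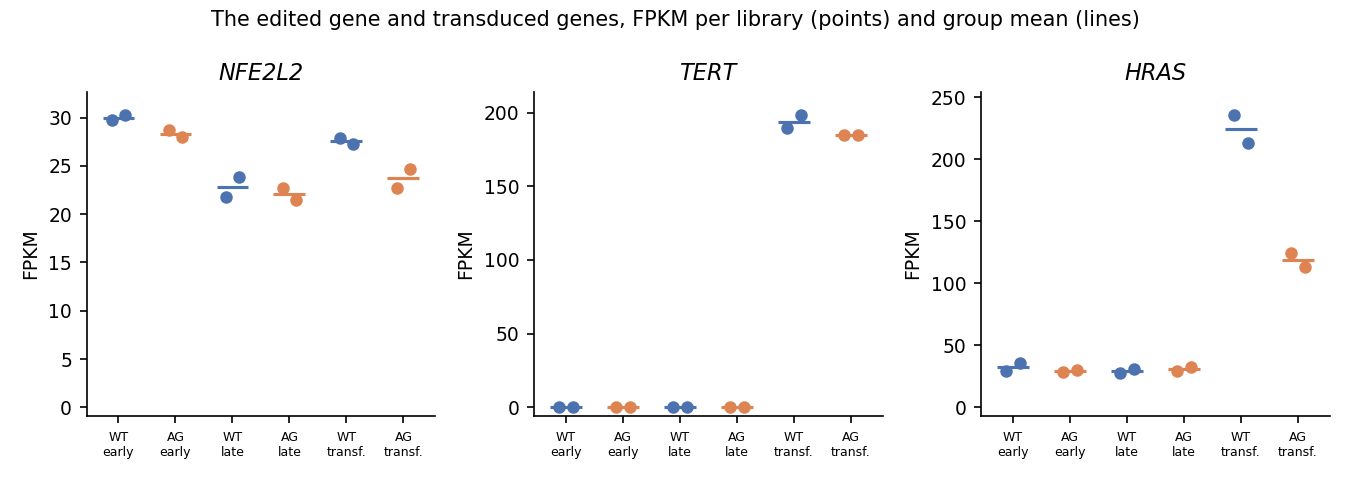
FPKM of NFE2L2, TERT and HRAS in each of the 12 libraries, by group. TERT reads 0 in the 8 MSC libraries and 185 to 198 in the 4 transformed libraries, and HRAS averages 224 in transformed WT and 119 in transformed AG.

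Cytokine genes were among the largest increases in transformed WT cells. IL1B went from 0.204 ± 0.14 to 1713 ± 117 FPKM (10.48, adjusted p = 1.6e-13), and IL6 from 0.143 ± 0.20 to 240.3 ± 11 (7.73, adjusted p = 7.5e-12). CSF3, a granulocyte growth factor, went from 0.259 ± 0.10 to 183 ± 8.7 (7.19, adjusted p = 7.2e-11), and the chemokines CXCL5 and IL8 rose by 6.46 and 6.30 (adjusted p = 2.2e-11 and 9.5e-12). S100A6 read 195 and 180.4 in early WT and was listed at 0 in both transformed WT libraries. STMN2, a neuronal microtubule regulator, fell from 98.8 ± 4.1 to 0.526 ± 0.046 (-6.03, adjusted p = 3.5e-12), IGFBP5 from 329 ± 6.7 to 8.42 ± 0.86 (-5.13, adjusted p = 2.0e-12), and CXCL12, a stromal chemokine, from 374 ± 29 to 12.5 ± 0.16 (-4.79, adjusted p = 1.4e-11). IGFBP2 (-5.86, adjusted p = 1.5e-10) and KRT19 (-5.42, adjusted p = 2.3e-11) fell too.

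In the lists, secreted factors mostly rose in transformed WT cells, as 27 of 35 rose, 8 fell and 0 did not pass (27 and 8 adjusted over the list alone), with PLAU from 95.5 ± 5.7 to 202 ± 13. Secreted factors shifted by a median of 1.96, or 1.85 less the median of all genes (camera adjusted p = 7.9e-06, adjusted p = 0.16 with an estimated correlation). For DNA replication, 28 of 31 rose, 0 fell and 3 did not pass (28 and 0 adjusted over the list alone), with FEN1 from 22.2 ± 0.93 to 60.5 ± 2.1. Replication genes shifted by a median of 0.76, or 0.65 less the median of all genes (camera adjusted p = 4.3e-06, adjusted p = 0.25 with an estimated correlation). For mitosis, 23 of 30 rose, 2 fell and 5 did not pass (23 and 2 adjusted over the list alone), with PLK1 from 40.8 ± 1.9 to 93.3 ± 3.5. Mitosis genes shifted by a median of 0.53, or 0.42 less the median of all genes (camera adjusted p = 0.001, adjusted p = 0.47 with an estimated correlation). Of TGF-beta and YAP targets, 14 of 19 rose, 3 fell and 2 did not pass (14 and 3 adjusted over the list alone), with F3 from 10.9 ± 1.0 to 288 ± 11. TGF-beta targets shifted by a median of 1.07, or 0.95 less the median of all genes (camera adjusted p = 2.1e-04, adjusted p = 0.16 with an estimated correlation). Neural markers mostly fell, as 0 of 6 rose, 5 fell and 1 did not pass (0 and 5 adjusted over the list alone). Neural markers shifted by a median of -1.73, or -1.85 less the median of all genes (camera adjusted p = 2.1e-04, adjusted p = 0.077 with an estimated correlation). Endothelial markers rose, as 6 of 6 rose, 0 fell and 0 did not pass (6 and 0 adjusted over the list alone), with FLT1 from 0.756 ± 0.44 to 9.78 ± 0.87. Endothelial markers shifted by a median of 1.22, or 1.11 less the median of all genes (camera adjusted p = 0.0075, adjusted p = 0.16 with an estimated correlation). Of the epithelial markers, 0 of 5 rose, 2 fell and 3 did not pass (0 and 2 adjusted over the list alone). Epithelial markers shifted by a median of -0.18, or -0.30 less the median of all genes (camera adjusted p = 0.014, adjusted p = 0.34 with an estimated correlation). Of unfolded protein response and ATF4 genes, 19 of 25 rose, 2 fell and 4 did not pass (19 and 2 adjusted over the list alone), with PSAT1 from 12.1 ± 0.74 to 40.8 ± 1.7. ATF4 genes shifted by a median of 0.60, or 0.49 less the median of all genes (camera adjusted p = 7.8e-04, adjusted p = 0.21 with an estimated correlation).

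Among NRF2 targets in transformed WT cells, 9 of 36 rose, 17 fell and 10 did not pass (9 and 17 adjusted over the list alone), with NQO1 from 276 ± 8.5 to 100.4 ± 5.2. NRF2 targets shifted by a median of -0.11, or -0.22 less the median of all genes (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation). Its median lay between -0.31 and -0.06 over the alternatives. On transformation in WT, limma called 7752 genes, 4919 higher and 2833 lower in transformed cells, and 1337 by at least 2-fold. With median-ratio scaling 7602 changed, 3794 higher and 3808 lower, and against late passage 9276 changed. Transformed cells also differed from MSC in growth factor, at 0 against 10 ng/mL.

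Transformed AG cells were compared with early-passage AG MSC in the same way. IL1B went from 2.50 ± 0.073 to 1142 ± 69 FPKM (8.35, adjusted p = 1.7e-12), and IL6 from 0.363 ± 0.063 to 380.1 ± 11 (8.13, adjusted p = 1.6e-11). CSF3 went from 0.481 ± 0.34 to 343 ± 0.36 (7.88, adjusted p = 6.3e-11), and ALDH1A3, a retinal dehydrogenase, from 0.666 ± 0.11 to 102 ± 7.8 (5.95, adjusted p = 2.4e-11). IL24 read 0.0698 and 0 in early AG and 54.95 and 46.9 in transformed AG (adjusted p = 6.3e-11). FOS fell from 30.6 ± 4.6 to 1.13 ± 0.18 (-3.88, adjusted p = 7.7e-09), RGS4 from 60.8 ± 8.0 to 5.37 ± 0.48 (-3.27, adjusted p = 4.4e-09), and STMN2 from 129 ± 18 to 12.8 ± 0.0043 (-3.23, adjusted p = 5.0e-10). GDF5, a joint growth factor (-3.18, adjusted p = 1.8e-09), MXRA5 (-3.14, adjusted p = 9.9e-10) and MSX1 (-2.997, adjusted p = 2.4e-09) fell as well.

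Secreted factors mostly rose in transformed AG cells, as 30 of 35 rose, 2 fell and 3 did not pass (30 and 2 adjusted over the list alone), with CXCL1 from 15.4 ± 1.4 to 489 ± 20.1. Secreted factors shifted by a median of 1.92 (camera adjusted p = 1.7e-13, adjusted p = 0.074 with an estimated correlation). In glycolysis and hypoxia, 22 of 28 rose, 1 fell and 5 did not pass (24 and 1 adjusted over the list alone). Glycolysis genes shifted by a median of 0.46 (camera adjusted p = 8.8e-06, adjusted p = 0.14 with an estimated correlation). For RAS and MAPK output in AG, 15 of 24 rose, 3 fell and 6 did not pass (15 and 4 adjusted over the list alone), with FOSL1 from 52.3 ± 1.4 to 204 ± 4.5. RAS output shifted by a median of 0.35 (camera adjusted p = 0.022, adjusted p = 0.47 with an estimated correlation). In WT, 14 of 24 rose, 7 fell and 3 did not pass (14 and 7 adjusted over the list alone), and this list passed there with median-ratio scaling (adjusted p = 0.045). RAS output shifted by a median of 0.48, or 0.37 less the median of all genes (camera adjusted p = 0.11). For mitosis in AG, 18 of 30 rose, 3 fell and 9 did not pass (18 and 3 adjusted over the list alone). Mitosis genes shifted by a median of 0.35 (camera adjusted p = 0.03, adjusted p = 0.6 with an estimated correlation). Endothelial markers rose in AG as well, as 6 of 6 rose, 0 fell and 0 did not pass (6 and 0 adjusted over the list alone). Endothelial markers shifted by a median of 0.72 (camera adjusted p = 0.022, adjusted p = 0.21 with an estimated correlation).

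Among NRF2 targets in transformed AG cells, 8 of 36 rose, 13 fell and 15 did not pass (9 and 13 adjusted over the list alone), a list call lost with a filter at 5 FPKM (median -0.06, adjusted p = 0.053, with 0.0076 to 0.053 over its alternatives). NRF2 targets shifted by a median of -0.07 (camera adjusted p = 0.03, adjusted p = 0.47 with an estimated correlation). Its median lay between -0.26 and -0.03 over the alternatives. On transformation in AG, limma called 6937 genes, 4501 higher and 2436 lower, and 994 by at least 2-fold. With median-ratio scaling 6977 changed, 3721 higher and 3256 lower, with quantile normalization 3150 were higher and 4063 lower, and against late passage 7389 changed.

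The change on transformation was compared between the genotypes by its interaction. CLEC2B stood at 54.2 ± 2.2 FPKM in transformed WT and 1.64 ± 0.49 in transformed AG (-4.30, adjusted p = 1.5e-07). Negative interactions were also found for ABI3BP (-3.73, adjusted p = 5.5e-08), DNER, a Notch ligand (-3.38, adjusted p = 1.1e-07), and EMILIN2, a matrix protein (-3.23, adjusted p = 1.8e-07). LUM, lumican, stood at 1.18 ± 0.26 in transformed WT and 22.1 ± 1.4 in transformed AG (5.03, adjusted p = 8.2e-08). S100A6, IL24 and MT1L also had positive interactions (adjusted p = 2.4e-11, 5.8e-09 and 1.8e-06) with transformed WT libraries listed at 0.

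Of the HOX genes, 10 of 10 were above 0, 0 below 0 and 0 did not pass (10 and 0 adjusted over the list alone). Their median interaction was 1.15 (camera adjusted p = 1.8e-05, adjusted p = 0.072 with an estimated correlation). The 5 reaching the filter without transformed AG (2 without any AG, so it partly set direction) were all above 0, median 1.17 (camera adjusted p = 0.001, adjusted p = 0.029 with an estimated correlation, over 2 tests). For DNA replication, 0 of 31 were above 0, 17 below 0 and 14 did not pass (0 and 19 adjusted over the list alone). Replication genes gave a median interaction of -0.39 (camera adjusted p = 1.3e-05, adjusted p = 0.42 with an estimated correlation). Among heat shock genes, 0 of 14 were above 0, 11 below 0 and 3 did not pass (0 and 11 adjusted over the list alone), with HSPA8 at -0.94 (adjusted p = 5.5e-07). Heat shock genes gave a median interaction of -0.50 (camera adjusted p = 1.8e-05, adjusted p = 0.42 with an estimated correlation). Among neural markers, 5 of 6 were above 0, 0 below 0 and 1 did not pass (5 and 0 adjusted over the list alone), with L1CAM at 4.73 (adjusted p = 5.6e-09). Neural markers gave a median interaction of 0.72 (camera adjusted p = 0.0066, adjusted p = 0.21 with an estimated correlation). Of the NRF2 targets, 13 of 36 were above 0, 8 below 0 and 15 did not pass (13 and 8 adjusted over the list alone), with SLC7A11 at -1.02 (adjusted p = 6.0e-06) and MGST1 at 1.27 (adjusted p = 2.1e-06). NRF2 targets gave a median interaction of 0.08 (camera adjusted p = 0.29). Its median lay between 0.06 and 0.14 over the alternatives. In limma's test 4611 genes had an interaction, 2316 above 0 and 2295 below, and with quantile normalization 2200 were above and 2441 below. Calls on transformation were shared by the genotypes for 3052 genes higher and 1411 lower (1781 and 555 expected), and 569 went in opposite directions.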

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

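The comparisons, the interaction tests, the gene lists and the rule for named genes were fixed before the data were examined. The explanations weighed here for 2 patterns, with their tests, were chosen only after the results were seen.

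Mitosis genes fell less with passage in AG than in WT, with an interaction above 0 for 30 of 30 genes and a median of 1.46. Library composition or scaling as the whole of it would have needed a median of 0.731 or less with median-ratio scaling, which gave 1.44 (95% interval 1.27 to 1.52) and argues against it. Every passage change smaller by 1 factor in AG would give matrix genes a median of -0.43, against -0.063 found (95% interval -0.34 to 0.28). Genes are not independent, so this argues only weakly against it. Another line difference or unequal late passages (numbers not given) cannot be told apart from the edit. Each genotype is its own line, and 5 of the 30 genes were already higher in AG at early passage. An effect of the recoded NRF2 on division at late passage remains only a hypothesis.

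Genes listed at 0 in 1 genotype included CBR1 in all 6 WT libraries and S100A6, IL24 and MT1L in both transformed WT libraries. Fragments given to an overlapping or neighbouring gene would have raised that gene, and 0 genes within 10 kb of these 4 gained at least 50% of the lost FPKM. Estimates failing by chance would leave genes at 0 in 1 library with the duplicate at 20 FPKM or more. Of the symbols counted, 0 did so. Cases at 0 in both libraries of a group came to 20 (transduced TERT in 4 groups, the only ones in AG). Small RNAs and other symbols not counted gave 81 cases at 0 in 1 library, so failure by chance stays open. Loss in the transformed WT line itself cannot be told apart from an effect of the edit, with 1 transformed group per genotype, and 7 genes (among them CTSZ, CYTL1, MT1L, NDN and S100A6) stood at 5 FPKM or more in the 4 WT MSC libraries and at 0 in both transformed WT libraries, and 0 genes did so in AG.

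Other results are listed because the interaction test set the genotypes apart, for 2304 genes with passage and 4611 with transformation. Genes whose change with passage was more positive in AG (log2 interaction) were KYNU 1.25, HGF 1.56, DLK1 2.12, G0S2 3.14, IL1B 2.74, IL6 2.03, IL32 1.95, DLGAP5 1.56, NUF2 1.65, PTTG1 2.20, HMGB2 1.82 and ASPM 1.46. More negative in AG were DHRS3 -3.49, PTGIS -2.58, LBH -2.38, IGFBP2 -2.34, TRIM55 -2.07, SULF1 -1.94, SCG2 -1.80, MEST -1.75, NTN4 -1.50, RGS4 -1.49, MMP3 -1.24, POSTN -0.93, ANXA10 -0.74 and F3 -0.66. HSD11B1 (13.8 FPKM in its highest group), MSC (14.6) and NUPR1 (5.59) also had a passage interaction, with a group listed at 0.

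On transformation, the interaction was positive for LUM 5.03, IGFBP2 4.33, TNFRSF11B 4.22, IGFBP5 4.18, KRT19 3.33, HGF 3.15, STMN2 2.80, CCL2 2.78, CXCL12 2.47, TRIM55 2.07, GDF5 1.38, MXRA5 1.32, MEST 1.01 and CSF3 0.68. It was negative for CLEC2B -4.30, ABI3BP -3.73, DNER -3.38, EMILIN2 -3.23, FAM84B -3.12, RGS4 -3.07, ZIC2 -2.94, IL1B -2.13, KRT8 -1.83, AKR1C1 -1.79, MMP3 -1.74, AKR1C2 -1.63, IL8 -1.50, CXCL5 -1.49, MSX1 -1.23 and HIST1H4A -1.02. Genes with a group listed at 0 were S100A6 (398 FPKM in its highest group), CBR1 (73.1), IL24 (50.9), MT1L (28.5) and DLK1 (6.83).

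Among the lists reported, medians with a camera call for the passage interaction were mitosis 1.46, DNA replication 0.93, secreted factors 0.62, lamina 0.60, osteogenic and chondrogenic 0.59, cholesterol synthesis 0.50, immediate early 0.38, RAS and MAPK output 0.33, NRF2 targets 0.22, TGF-beta and YAP targets -0.17, glycolysis and hypoxia -0.22 and epithelial markers -1.12. For transformation they were HOX 1.15, osteogenic and chondrogenic 0.88, neural 0.72, glycolysis and hypoxia 0.14, proteasome -0.15, mitosis -0.20, DNA replication -0.39 and heat shock -0.50, where the osteogenic and proteasome lists lost theirs with median-ratio scaling (adjusted p = 0.0623 and 0.0604). With an estimated correlation, 0 of these 20 lists passed.

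A signal outside the naming rule, which leaves out hyphenated symbols, was that of RNA5-8S5. It had at least 71576 FPKM in each of the 4 late-passage libraries and at most 16538 in each of the other 8.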

How the results depend on the processing

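Of 318 alternative values for 20 results, 302 kept their side of the threshold or stayed within the bounds set for a value without a test, 15 moved and 1 lost its call. Among the 302, 3 medians of the NRF2 target list without a call changed sign: for passage in AG, 0.07 became -0.0401 with quantile normalization and -0.106 without near copies, and for passage in WT, -0.07 became 0.0213 with median-ratio scaling. Added after seeing the data were the runs without symbols on several lines, without lines marked FAIL and without NRF2 targets that have near copies. In the leave-one-out runs the lone library left in a group was assumed to vary like the other groups. The early-passage genotype count of 2026 became 1092 in a fit of only the groups compared, which has fewer samples, and 1232 to 1521 leaving out 1 library of the groups compared (1232 without AG replicate 1 and 1237 without AG replicate 2). The NRF2 target list of transformed against early AG cells had a median of -0.07 and lost its call with a filter at 5 FPKM (-0.0603, adjusted p = 0.053, with 0.0076 to 0.053 over its alternatives), and the cause was not tested. The slope of the AG on the WT passage change, 0.631, became 0.585 with a pseudocount of 0.1, 0.623 with no filter, 0.651 with a filter at 5, 0.623 with median-ratio scaling and 0.599 to 0.651 leaving out 1 library.

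The other counts leaving out 1 library were 4136 to 4432 between genotypes at late passage, 4291 to 4561 after transformation, 7151 to 7271 and 5928 to 6385 for passage in WT and AG, 6644 to 6957 and 5705 to 5932 for transformation in WT and AG, and 1738 to 1991 and 3640 to 4163 for the interactions. With the replicate block, which pairs libraries that share only a number (correlations of -0.197 to 0.261), the counts in the same order, early passage first, were 1864, 5235, 5636, 8018, 7158, 7663, 6885, 2201 and 4544, and the slope 0.631. Against late instead of early passage, transformation changed 9276 genes in WT (6192 higher) and 7389 in AG (5277 higher). Of 1617 alternative values for 111 named gene changes, 1607 kept their side of the threshold, 8 lost their call, 2 gained one and 0 called changes reversed (NFE2L2 at late passage, not called, went from -0.0409 to 0.0213 without WT late replicate 2), and the 8 lost were runs without 1 library, among them runs for NFE2L2 and H3F3A. Lists with a camera call numbered 11 at early passage (8 to 13 over the alternatives), 12 at late passage (11 to 16), 12 after transformation (10 to 13), and 13 (11 to 17) and 8 (4 to 10) for the interactions. Depth limits genes with low FPKM, where the log2(FPKM + 1) scale also shrinks changes.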

Other observations

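Metallothioneins, which bind zinc and copper, were looked at after MT1L was seen at 0 in transformed WT cells. Of the other 6 measured, 5 were higher and 0 lower in transformed AG than transformed WT cells, with a median of 0.89 (adjusted p = 0.0234, adjusted p = 0.152 with an estimated correlation). On transformation these 6 rose in AG, with a median of 1.60 (adjusted p = 0.00614, adjusted p = 0.118 with an estimated correlation), while in WT 3 rose and 1 fell, with a median of 0.38 (adjusted p = 0.661). The interaction had a median of 1.29 (adjusted p = 0.00614, adjusted p = 0.118 with an estimated correlation). This family and the S100 genes were tested only after their values had been seen, and p was adjusted over 18 tests.

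S100 genes at 1q21 encode small calcium-binding proteins. S100A4 fell by 4.67 in WT (adjusted p = 2.1e-08) and by 0.86 in AG (adjusted p = 0.0058). Besides S100A4 and S100A6, seen first, 3 of 7 fell and 0 rose on transformation in WT (median -0.0825, adjusted p = 0.0356). In AG 3 fell and 1 rose (median -0.204, adjusted p = 0.129). The AG minus WT median was -0.144 at early passage (adjusted p = 0.0356) and 0.27 when transformed (adjusted p = 0.373). None passed with an estimated correlation (0.321 or more).

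Imprinted genes may have been lower in AG as a class, a hypothesis drawn, after values were seen, from MEST, DLK1 and NDN. Of 23 measured, 3 were higher and 10 lower at early passage, 5 and 11 at late passage, and 6 and 6 after transformation. Without these 3 genes, and adjusted over the 3 states only, camera gave adjusted p = 0.0261 at early passage, adjusted p = 0.0960 at late passage and adjusted p = 0.851 after transformation (0.190, 0.239 and 0.876 with an estimated correlation), so a lower level of the class in every state was not borne out.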
